A study of Homo sapiens with 4 samples.

How the data were processed

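Total RNA from MIA PaCa-2 cells was labelled with biotin and hybridised to 4 one-colour Affymetrix arrays, 2 from cells given scramble siRNA (control a and b) and 2 from cells given siRNA against KMT2D (a and b). Per the labels' protocols, cells were transfected at 50% confluence with 50 nM siRNA, transfected again after 24 h and harvested 24 h after that, and RNA was purified with TRIzol and a column. The authors deposited a series table of intensity values on a linear scale, and the submitters' processing notes name Affymetrix Expression Console, with no version. The summarization algorithm is not given in the sources used here. On each array the mean after trimming 2% of values at either end was close to 500 (500.1), and the values ran from 0.0576 to 50085. The deposited intensity values were used with no further normalization as log2(intensity + 1), so fold changes are on that scale and understate the change of dim genes.

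The table held 54675 probe sets, of which 62 were array controls and were left out of the tests, leaving 54613. Names came from the platform annotation given for this work, with symbols compared through Entrez gene IDs with a current human gene table. Of the tested probe sets 41091 had 1 gene symbol, 1801 had several and 11721 were unnamed here and were not analysed by name; 0 symbols needed updating. A gene was represented by the 1-symbol probe set with the highest mean over all 4 arrays, which gave 19775 genes, and other probe sets of a gene can differ. Among 1390 other probe sets that were called for a called gene, 102 (7.34%) had the opposite sign. Probe sets shared with a close paralog cannot separate the transcripts of the paralogs.

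Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The design fixed before the data were examined had the group as its only term, all 4 arrays, no block and 1 variance prior for all probe sets. A prior that follows the mean intensity, with robust estimation (the intensity-trend fit), was listed in advance as another fit. Because the designed fit called 0 genes, the genes described come from the intensity-trend fit, a choice made after that count was seen. An exact permutation test of 2 arrays against 2 cannot give a p under 0.333 and was not used.

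Genes were named by a rule fixed in advance: KMT2D and each measured member of the KMT2 complexes; the 12 genes with the largest rise and the 12 with the largest fall among called genes whose arrays did not overlap and whose higher group was at or above the median level; 4 members with the smallest adjusted p in each list that camera called and in the glycolysis, fatty acid synthesis and cholesterol lists; and at most 2 in other lists. The part on largest changes was applied to the intensity-trend fit, since 0 genes met it in the designed fit and 3812 met it in the other, and members of lists were ranked by the designed fit. Over all, 37 gene lists written in advance covered chromatin complexes, glucose, lipid and amino acid metabolism, cell cycle, stress, signalling and markers of other cell types, and 706 of their 783 entries were measured. Lists were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 37 lists, with camera at an estimated correlation and with fry. With an estimated correlation camera had only 2 residual degrees of freedom, and its smallest adjusted p over the lists was 0.789. A call lost there therefore does not show that correlation between genes accounts for it. List medians were also set against 10000 random lists matched on mean log2 value in 20 bins.

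The fits were tested on simulated data with the levels of the real arrays, 19775 genes and 50 genes changed at each fold. The simulated spread was modelled on the real duplicates, but its variance was larger on average, since it was also varied from gene to gene. A list of 25 genes was shifted as well, and calls in it count as true. The changed genes and the list were drawn from genes at or above the median level. They were far fewer than the 3860 genes called on the real arrays, and the adjustment for many tests depends on that share. Noise was independent between genes, and its spread followed brightness as the intensity-trend fit assumes. The simulation therefore cannot settle the choice of fit or the error rate of camera for correlated genes. The intensity-trend fit made 134 calls, 10 of them false, and 0 calls when nothing was changed, and camera found the shifted list (adjusted p = 3.48e-13) and 0 of 36 others. Alternatives covered the normalization, filters and a floor on dim values, the variance prior, the added constant, the replicate letter as a block, each array left out in turn, the probe set standing for a gene, a minimum fold and the list test. Raising dim values to the 25th percentile cut the calls of the intensity-trend fit from 3860 to 1612 genes. For genes above that floor it left log2 changes as they were and moved only the variance prior and the adjustment. A call lost there does not mean that a bright gene rests on dim signal. The replicate letters were not used to pair arrays. No array date or batch was given, and siRNA sequences were not used here.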

Results

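Expression profiles were recorded from MIA PaCa-2 cells, an established human pancreatic carcinoma line, after KMT2D had been silenced with siRNA. KMT2D is a histone H3 lysine methyltransferase that acts mainly at enhancers. Cells received 50 nM of siRNA against KMT2D or of a scramble siRNA, were transfected a second time after 24 h and were lysed for RNA 24 h later. Each of the 2 groups had 2 arrays, named a and b, which made 4 arrays with 54675 probe sets each. The median signal was 61.1 and 71.0 on the control arrays and 65.7 and 62.8 on the KMT2D siRNA arrays. Duplicate arrays correlated with r = 0.950 in the control group and 0.950 in the KMT2D siRNA group across probe sets, which are not independent replicates, against 0.937 to 0.942 between groups. Errors given with signals are SDs over 2 arrays (n = 2 per group), and those given with log2 changes are standard errors. The submitters described the arrays as technical duplicates, so the p-values measure only the spread between duplicate arrays, and the small number of arrays limits the precision.

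The comparison addressed which transcripts change when KMT2D is depleted, in a study concerned with glucose and lipid metabolism. KMT2D itself, on chromosome 12 (Entrez gene 8085), was lower on both KMT2D siRNA arrays than on both control arrays. Its brightest probe set went from 996 ± 42.0 in control cells to 207 ± 1.38 after KMT2D siRNA, a 4.79-fold lower signal and a log2 change of -2.26. The next brightest probe set had signals of 125 ± 5.90 and 98.6 ± 22.7 (log2 change -0.36) and the one after it 148 ± 56.4 and 62.3 ± 2.62 (-1.18). The 3 remaining KMT2D probe sets had mean signals between 5.74 and 35.5 in every group, where duplicate arrays differed as much as the groups did. In the limma fit with 1 variance prior for all probe sets, the brightest probe set had an adjusted p of 0.192 (standard error 0.17). In the limma fit with an intensity trend in the prior its adjusted p was 1.84e-04 (standard error 0.15), and those of the next brightest probe set and the one after it were 0.574 and 0.0816. Over 13 alternatives to the first fit, the adjusted p of the brightest probe set ran from 1.84e-04 to 0.461, with log2 changes between -2.30 and -2.18. The mean of all 6 KMT2D probe sets did not pass in the intensity-trend fit (log2 change -0.44, adjusted p = 0.616).

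Depletion of KMT2D came with changes in 3860 of 19775 genes in the intensity-trend fit, of which 1854 rose and 2006 fell. Of these, 1016 rose and 1452 fell by at least 1.5-fold, and 351 rose and 681 fell by at least 2-fold. The designed limma fit with 1 variance prior called 0 genes and 0 probe sets, with a smallest adjusted p of 0.1 over genes and 0.192 over probe sets. At an unadjusted p under 0.05 that fit had 2003 genes higher and 2423 lower, and 3944 probe sets higher and 4929 lower. Simulated data for this comparison had 19775 genes, and the changed genes were drawn from those at or above the median level. The fit with 1 prior recovered 0% of those changed 8-fold. The intensity-trend fit recovered 90% at 8-fold, 80% at 4-fold, 56% at 2-fold and 12% at 1.5-fold, with 10 false calls among 134. The simulated noise followed brightness as that fit assumes, so these rates do not settle which fit is right for the real arrays. Its variance was larger on average than between the real duplicates, and far fewer genes were changed than the 3860 called. The rates of recovery on the real arrays may therefore differ. Restricted to the 12154 genes at or above the median level, the fit with 1 prior called 1237 genes higher and 1638 lower, and 2596 of these 2875 genes were also called by the intensity-trend fit. In 10920 genes (55.2%) both arrays of one group lay above both of the other, against 33.3% for 4 exchangeable arrays, a share that any difference between the cultures behind technical duplicates also raises. With 1 array left out, the spread comes from the duplicates of the other group alone. Among the brightest probe sets the SD between duplicates was 0.176 for control and 0.0854 for KMT2D siRNA arrays. The intensity-trend fit called fewer genes without either KMT2D siRNA array and more without either control array. A count that drops without an array, here and below, therefore does not show that the changes rest on that array. In what follows, rose, fell and changed refer to the intensity-trend fit on all genes, and none of those genes passed the designed fit.

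**Figure D1:**
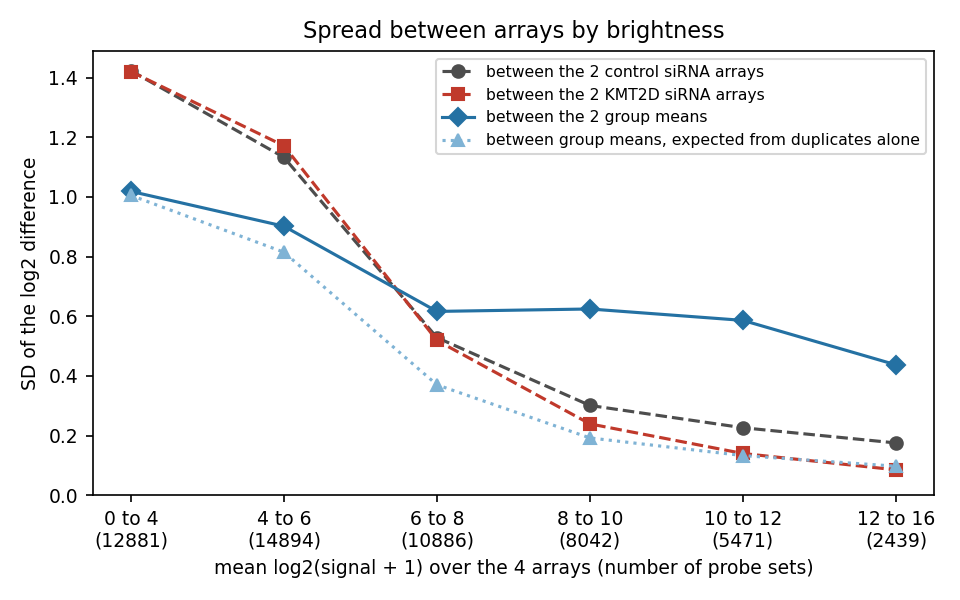
SD of log2 differences between arrays (vertical axis) in 6 bins of mean log2(signal + 1) (horizontal axis), between the 2 control arrays, between the 2 KMT2D siRNA arrays and between the group means, with the SD of group means that duplicates alone would give. The SD between control duplicates, which are single arrays, ran from 1.42 in the dimmest bin to 0.176 in the brightest. That between group means ran from 1.02 to 0.437, against 1.01 and 0.0976 expected for such means from duplicates alone.

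The largest rises were seen in genes of varied function. CMBL, a cysteine hydrolase, went from 1264 ± 153 to 9454 ± 616 (7.49-fold), while another bright probe set of the gene rose by 0.40 on the log2 scale. MEST, an imprinted gene of the alpha/beta hydrolase fold family, went from 106 ± 11.4 to 1197 ± 14.6 (11.2-fold). TNFSF10, which encodes the death ligand TRAIL, rose 6.53-fold from 407 ± 11.2 to 2664 ± 97.2, and PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis, rose 6.35-fold from 413 ± 23.1 to 2627 ± 76.1. The oxytocin receptor OXTR rose 7.20-fold, CCM2L 7.59-fold and the calcium-regulated transcription factor NFATC2 7.11-fold, while the other CCM2L probe set had a log2 change of -0.31 (adjusted p = 0.616). CRIP2, a LIM domain protein, rose from a control signal near the noise (11.8 ± 1.21 to 219.9 ± 25.4), as did the Wnt ligand WNT4 (5.55 ± 1.60 to 67.1 ± 2.20), the chemokine CCL20 (8.59 ± 4.94 to 72.1 ± 10.6), the matrix protein gene TNN (8.81 ± 2.88 to 66.7 ± 0.581) and the long noncoding RNA LINC00482 (13.2 ± 0.703 to 96.8 ± 3.92), and the size of these rises is not well determined. In the dimmest bins duplicates differed by over 2-fold in 33.0% and 44.8% of control probe sets. The adjusted p of these 12 genes ran from 2.17e-05 for CMBL to 0.0233 for TNN. WNT4, CCL20, TNN and LINC00482 did not pass without KMT2D siRNA array a (adjusted p = 0.0922, 0.151, 0.139 and 0.0919) or array b (0.0893, 0.117, 0.147 and 0.11). With the mean of their probe sets WNT4 (1.17, adjusted p = 0.313) and NFATC2 (1.25, 0.156) did not pass, and the other 2 WNT4 probe sets had log2 changes of 0.21 and -0.11. Another NFATC2 probe set rose by 2.79 on the log2 scale, and its dim ones changed by 0.059 and -0.68 without passing. With dim values raised to the 25th percentile NFATC2 (adjusted p = 0.126) and CCM2L (0.0524) did not pass, and NFATC2 had log2 changes of 2.17 and 3.49 without control array a and b, against 2.83 with all arrays.

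Among the genes with the largest falls, DESI2, of the deSUMOylating isopeptidase family, went from 10151 ± 886 to 971 ± 7.47 (10.4-fold lower), while the log2 changes of its other 4 probe sets ran from -2.59 to -0.11. CYBRD1, a ferric reductase, fell 11.1-fold from 5029 ± 187 to 455 ± 62.8, although its other probe set had a log2 change of 0.015. TTC7B, part of a complex that anchors a phosphatidylinositol kinase at the plasma membrane, went from 1104 ± 59.5 to 103 ± 7.79 (10.7-fold), and CENPQ, a kinetochore protein, from 778 ± 313 to 61.6 ± 11.4 (12-fold). The chemokine CCL22 and the membrane ubiquitin ligase MARCHF3 fell from 264 ± 14.9 to 20.1 ± 7.24 and from 346 ± 44.7 to 40.8 ± 45.6. Falls to signals near the noise were also those of LOC100289495 (206 ± 45.3 to 16.2 ± 1.63), LRRC1 (232 ± 6.38 to 31.6 ± 32.4), LRP12 (111 ± 21.7 to 14.4 ± 14), LCAT (115 ± 30.8 to 11.5 ± 4.06), which esterifies cholesterol in plasma, and DOCK9-DT (98.4 ± 40.3 to 10.6 ± 4.89), a divergent transcript. The size of these 7 falls, CCL22 and MARCHF3 included, is not well determined. MAPKAP1, a subunit of an mTOR complex, had a 10.1-fold lower signal in its brightest probe set, but 2 other probe sets of the gene rose, by 2.06 and 1.68 on the log2 scale. The adjusted p of these 12 genes ran from 1.21e-05 for DESI2 to 0.0254 for LRP12. LRP12 did not pass without control array a (adjusted p = 0.0507), control array b (0.0838) or KMT2D siRNA array b (0.0519), and the log2 changes of MARCHF3, LRRC1 and LRP12 (-3.69, -3.33 and -3.23) were -2.22, -2.07 and -4.32 without KMT2D siRNA array a and -5.17, -4.58 and -2.13 without array b. With dim values raised to the 25th percentile MARCHF3 (-3.23, adjusted p = 0.187), LRRC1 (-2.88, 0.16), CENPQ (-3.59, 0.0618), LRP12 (-2.37, 0.0638) and DOCK9-DT (-2.39, 0.089) did not pass. DOCK9-DT did not pass without control array b (0.0827) or KMT2D siRNA array b (0.0506). With the mean of their probe sets LCAT (-1.68, adjusted p = 0.203), LRRC1 (-2.23, 0.161), DOCK9-DT (-1.61, 0.163) and MAPKAP1 (-0.0046, 0.993) did not pass, and the other LCAT probe set had a log2 change of -0.13.

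**Figure D2:**
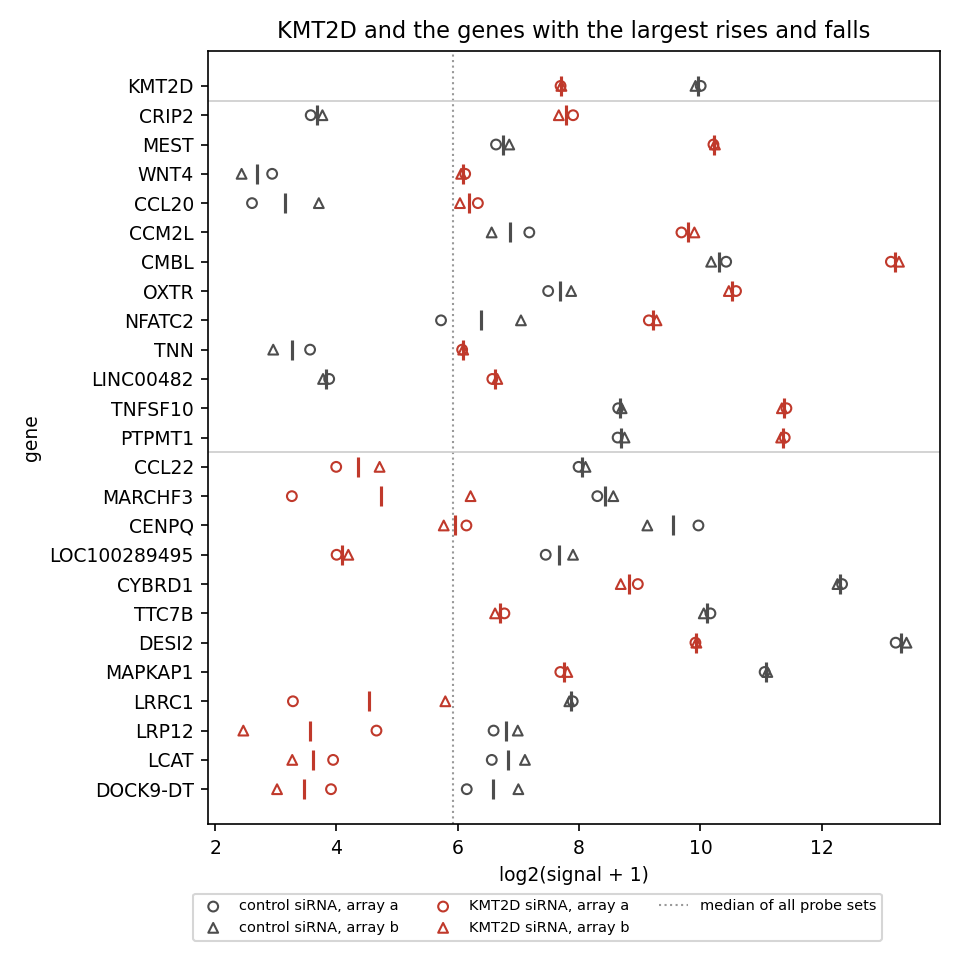
log2(signal + 1) on each of the 4 arrays (horizontal axis) for KMT2D and the 12 genes with the largest rises and the 12 with the largest falls (vertical axis), with group means as vertical bars. The dotted line marks the median of all probe sets, 5.93, below which the control means of CRIP2, WNT4, CCL20, TNN and LINC00482 lie.

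Genes of the KMT2 methyltransferase complexes changed in both directions. Of 18 measured members, the siRNA target KMT2D included, 5 fell and 2 rose, and adjusted over the list alone 5 fell and 3 rose. Whether this share exceeds that of equally bright genes was not tested. Besides KMT2D, the falls were in the shared core subunits DPY30 (5856 ± 662 to 2889 ± 84.4, log2 change -1.01 ± 0.10), ASH2L (1394 ± 50 to 713 ± 27.8, -0.97 ± 0.12) and RBBP5 (-0.60 ± 0.15) and in the methyltransferase KMT2A (-0.64 ± 0.11). The core subunit WDR5 rose from 1007 ± 22.3 to 1921 ± 104 (0.93 ± 0.11), as did PAXIP1, a partner of KMT2D and KMT2C (0.82 ± 0.13). The closest relative of KMT2D, KMT2C, had signals of 2654 ± 347 and 2868 ± 62.7, with a log2 change of 0.12 ± 0.11 that did not pass. Nor did KMT2B (-0.067), SETD1A (0.64), SETD1B (0.10), MEN1 (0.51), NCOA6 (0.23, though its other probe set fell by 1.21, adjusted p = 0.0396), PAGR1 (0.51), HCFC1 (0.16), CXXC1 (0.082), WDR82 (0.24) or the demethylase KDM6A (0.043), whose brightest probe set was near the noise at 5.80 in control cells. KMT2A and RBBP5 did not pass without KMT2D siRNA array a (adjusted p = 0.0861 and 0.136) or array b (0.055 and 0.16), which left 3 falls, and without control array a and b 5 and 4 members rose. The other WDR5 probe set had a log2 change of 0.35 (adjusted p = 0.23), and KMT2A did not pass with the mean of its probe sets (-0.059, adjusted p = 0.949). Among the other KMT2A probe sets the only call was a fall of 1.22 on the log2 scale. With dim values raised DPY30 (adjusted p = 0.0557), PAXIP1 (0.124) and CBX2 (0.0789) did not pass. Their log2 changes stayed the same, since these genes lie above the floor, and only the variance prior and the adjustment over genes moved. With each array centred on its median KMT2A (adjusted p = 0.0553) and RBBP5 (0.102) did not pass. Of 19 genes for histone demethylases acting on the same lysine and for Polycomb proteins, 3 rose and 1 fell, with the same counts adjusted over the list alone. The Polycomb subunit EED went from 4046 ± 5.73 to 1619.6 ± 4.51 (-1.32 ± 0.09), while its other probe set changed by 0.81 and did not pass, and CBX2 went from 252 ± 47.7 to 675 ± 80.3 (1.42 ± 0.19). The histone-binding RBBP4 (0.66) and the Polycomb partner MTF2 (1.15) were the other rises, and members named here and below to complete a count of 5 or fewer were chosen after their values were seen. Leaving out either control array gave 2 falls in that list, and CBX2 (0.17, adjusted p = 0.814) and EED (-0.26, 0.641) did not pass with the mean of their probe sets. The limma camera test gave adjusted p = 0.985 for the KMT2 complexes and 0.79 for the other list.

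Genes of mitosis were lower after KMT2D siRNA, with 20 of 33 measured members falling and 1 rising, and a median log2 change of -0.60. PRC1, which bundles microtubules of the central spindle, went from 5392 ± 517 to 1037 ± 37 (-2.37 ± 0.10). BIRC5, the chromosomal passenger protein survivin, fell from 3047 ± 153 to 815 ± 50.3 (-1.90 ± 0.11), TOP2A, the topoisomerase that untangles sister chromatids, from 6979 ± 429.8 to 2043 ± 41.7 (-1.77 ± 0.08), and KIF11, the bipolar spindle motor, from 2853 ± 88.4 to 1353 ± 9.80 (-1.08 ± 0.09). CDC20, an activator of the anaphase-promoting complex, was the member that rose (0.31). Adjusted over the list alone, 23 fell and 1 rose, and camera called the list lower (adjusted p = 7.67e-06). With an estimated correlation between genes (0.48 for this list) the camera call was lost (adjusted p = 0.789). That setting called 0 lists on 2 residual degrees of freedom, so it cannot separate correlation from low power. Fry, the other list test, did not call the mitosis list either (adjusted p = 0.0817). Over 18 alternatives the adjusted p ran from 2.85e-09 to 0.789. Without KMT2D siRNA array a 14 mitosis genes were lower and without array b 12, and without control array a the median was -0.36 and 3 rose. The actin 3'/5' ratio, a sign of RNA integrity, was 2.13 and 1.91 on control arrays a and b and 1.56 and 1.55 on the KMT2D siRNA arrays, while the GAPDH 3'/5' ratio was 0.878 and 0.932 against 0.874 and 0.854.

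Of 34 measured genes of the G1/S transition and DNA replication 6 rose and 6 fell, with the same counts adjusted over the list alone (median -0.045, camera adjusted p = 0.79). CDC45, part of the replicative helicase, fell from 593 ± 26.5 to 182 ± 29 (-1.70 ± 0.19), and the origin licensing factor CDC6 fell from 849.6 ± 89 to 324 ± 9.75 (-1.39 ± 0.15). The balance depended on single arrays: 12 rose and 5 fell without control array a (median 0.13), 6 and 12 without control array b (median -0.27), 2 and 2 without KMT2D siRNA array a and 2 and 3 without array b. Among 7 cyclin-dependent kinase inhibitors 1 rose and 1 fell, likewise when adjusted over the list alone (camera adjusted p = 0.985). CDKN1B, which encodes p27, went from 5401 ± 481 to 11725 ± 364 (1.12 ± 0.08), and CDKN3, a phosphatase of cyclin-dependent kinases, from 6309 ± 108 to 3932 ± 101 (-0.68 ± 0.08).

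Genes of glucose transport and glycolysis were higher by camera, with 11 of 22 measured members rising and 2 falling and a median log2 change of 0.27. The glucose transporter SLC2A3, whose close paralog SLC2A14 can share its probes, went from 2342 ± 312 to 5947 ± 82.4 (1.35 ± 0.10), and its other probe sets had log2 changes of 1.80 and 0.34. PFKFB4 and PFKFB3, which set the level of the activator of phosphofructokinase, moved apart: PFKFB4 rose from 313 ± 15 to 654 ± 41.5 (1.06 ± 0.15) and PFKFB3 fell from 1887 ± 291 to 835 ± 41.3 (-1.17 ± 0.13). ENO2, the neuronal form of enolase, fell from 938 ± 138 to 409 ± 45.2 (-1.19 ± 0.16), and ENO1, the widespread form, which was singled out after its values were seen, rose by 0.67. Adjusted over the list alone, 13 rose and 2 fell, and camera gave adjusted p = 0.0309. With an estimated correlation that call was lost (adjusted p = 0.789), although the estimate for this list, -0.0092, was below the preset 0.01. That setting called 0 lists on 2 residual degrees of freedom, so the loss does not show an effect of correlation. Nor did fry call the glycolysis list (adjusted p = 0.0589). Over 18 alternatives the adjusted p ran from 7.53e-04 to 0.789. The count of rises was 4 without KMT2D siRNA array a and 4 without array b, and 6 after quantile normalization, and PFKFB4 did not pass with the mean of its probe sets (0.35, adjusted p = 0.635), nor PFKFB3 (0.0685) and ENO2 (0.0775) with dim values raised. The median mean log2 value of the list was 11.6. Probe sets in the bin from 10 to 12 had a median log2 change of -0.0055, and those in the brightest bin one of 0.20. Random lists matched on brightness had a median change of 0.096. The actin and GAPDH 3'/5' ratios were as given for mitosis. The glucose and lipid lists were picked in the knowledge that the study concerned metabolism, so they are not independent evidence of a direction.

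Genes of mitochondrial energy metabolism did not pass camera. Of 19 measured members of the tricarboxylic acid cycle 8 rose and 1 fell (9 and 1 adjusted over the list alone), and of 27 members of oxidative phosphorylation 10 rose and 4 fell (13 and 4 adjusted over the list alone). IDH3G, a subunit of isocitrate dehydrogenase, went from 1842 ± 101 to 3554 ± 33.6 (0.95 ± 0.09), and DLST, of the oxoglutarate dehydrogenase complex, from 3819 ± 339 to 2316 ± 66 (-0.72 ± 0.10). COX6C, a cytochrome oxidase subunit, rose by 0.75 ± 0.07, and NDUFB5, of respiratory complex I, changed by -0.56 ± 0.06. The ATP synthase subunits ATP5F1B (-0.60) and ATP5PO (-0.42) and the electron carrier CYCS (-0.39) were the other falls. Camera gave adjusted p = 0.0814 for the cycle and 0.0825 for oxidative phosphorylation, and with a variance trend it called both higher (0.0225 and 0.0149), as it did without control array a (0.0429 for each). With an estimated correlation the adjusted p was 0.853 and 0.789. Of random lists matched on brightness 10.09% and 11.24% had medians as high. The rises in the oxidative phosphorylation list numbered 2 without KMT2D siRNA array a, 3 without array b and 4 after quantile normalization, and those in the tricarboxylic acid cycle 2, 2 and 5. The falls in oxidative phosphorylation numbered 2 with either of these arrays left out and those in the cycle 2 without control array b. In the pentose phosphate pathway 3 of 9 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.634). PRPS2, which makes phosphoribosyl pyrophosphate, fell from 6020.2 ± 739 to 3526 ± 68.3 (-0.77 ± 0.10), whereas RPE (0.55 ± 0.08), TALDO1 (0.46) and TKT (0.36), of the non-oxidative branch, rose. The other bright RPE probe sets rose by 0.56 and 0.71 on the log2 scale, and its dim one changed by -0.28 without passing. RPE did not pass without KMT2D siRNA array b (adjusted p = 0.0553) or with the mean of its probe sets (0.39, adjusted p = 0.0951), nor DLST (0.0643) and PRPS2 (0.082) with dim values raised. Members of that pathway that rose numbered 1 and 0 without KMT2D siRNA array a and b, and 2 fell without control array b.

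Enzymes of fatty acid and triglyceride synthesis changed in both directions, with 3 of 23 measured members rising and 6 falling (median -0.16). ACACA, the acetyl-CoA carboxylase that commits carbon to fatty acids, went from 1693 ± 44 to 4032 ± 14.1 (1.25 ± 0.09), while its other probe set had a log2 change of -0.50 (adjusted p = 0.0509) and the mean of both one of 0.37 (0.0555). Fatty acid synthase, FASN, went from 432 ± 76.4 to 1001 ± 36 (1.22 ± 0.16). ACLY, which supplies cytosolic acetyl-CoA, fell from 10199 ± 724 to 5792 ± 188 (-0.81 ± 0.08), and the acyl-CoA synthetase ACSL1 fell from 1554 ± 174 to 714 ± 11.4 (-1.12 ± 0.13). The remaining rise was DGAT2 (0.64), of triglyceride synthesis. Adjusted over the list alone, 4 rose and 7 fell, and camera gave adjusted p = 0.55. With either KMT2D siRNA array left out 2 rose and 3 fell, and the median was -0.35 without KMT2D siRNA array a, -0.064 without array b and -0.026 without control array b. Of 19 measured genes of cholesterol synthesis and uptake 2 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.475). INSIG1, which holds back sterol regulatory proteins in the endoplasmic reticulum, rose from 1125 ± 124 to 2651 ± 169.6 (1.24 ± 0.12). The late synthesis enzymes DHCR7 and MSMO1 changed by 0.46 ± 0.11 and -0.47 ± 0.10, and TM7SF2, with a log2 change of 0.44 ± 0.14, did not pass. DHCR7 and MSMO1 did not pass without KMT2D siRNA array a (adjusted p = 0.209 and 0.0933) or array b (0.184 and 0.166), which left 1 rise and 0 falls in that list, and without control array a 4 rose. DHCR7 did not pass with the mean of its probe sets (0.34, adjusted p = 0.105), nor DHCR7 (0.098) and MSMO1 (0.132) with centred arrays, nor FASN (0.0744) and MSMO1 (0.0623) with dim values raised.

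Genes of fatty acid oxidation and lipid droplets showed 10 rises and 2 falls among 26 measured members (11 and 3 adjusted over the list alone). The electron transfer flavoprotein subunit ETFB went from 1586 ± 85.2 to 3444 ± 172 (1.12 ± 0.10) and its dehydrogenase ETFDH from 342 ± 35.9 to 631 ± 20.2 (0.89 ± 0.16). The falls were in the beta-oxidation enzymes ECI1 (-0.60) and HADH (-0.73). Camera gave adjusted p = 0.287, and fry, which asks whether the genes move on balance one way without comparing them with other genes, gave 0.0471. The rises numbered 2 without KMT2D siRNA array a and 3 without array b, with 1 fall each, and ETFDH did not pass then (adjusted p = 0.055 and 0.0724). Of 13 genes of fatty acid uptake and binding 2 rose, the lipoprotein receptor LRP8 (1.16 ± 0.23) and the transporter SLC27A5 (0.71), also when adjusted over the list alone (camera adjusted p = 0.79). The lipase LPL had signals of 28.7 ± 3.31 and 81.2 ± 9.33 (log2 change 1.47 ± 0.48, adjusted p = 0.0704), and LRP8 did not pass without KMT2D siRNA array b (0.111). The uptake list had 1 rise without control array b, 1 without KMT2D siRNA array a and 0 without array b. ETFDH (adjusted p = 0.0612) and LRP8 (0.117) did not pass with dim values raised.

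In serine, glycine and one-carbon metabolism 4 of 11 measured members fell and 1 rose (5 and 1 adjusted over the list alone). PHGDH, the first enzyme of serine synthesis, went from 2992 ± 70.4 to 1156 ± 32.4 (-1.37 ± 0.10), and ALDH1L2, a mitochondrial folate enzyme, from 346 ± 64.4 to 102 ± 25.8 (-1.76 ± 0.27). PSAT1 (-0.39) and the glycine decarboxylase GLDC (-0.71) also fell, and PSPH, which completes serine synthesis, rose (0.63). Camera gave adjusted p = 0.388 for the list, and without KMT2D siRNA array a and array b, 3 and 3 members fell and 0 rose, while without control array b 3 rose. ALDH1L2 did not pass with the mean of its probe sets (-0.99, adjusted p = 0.0914) or with dim values raised (0.0914).

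Ribosomal protein genes were slightly higher, with 12 of 20 measured members rising and 0 falling and a median log2 change of 0.25. RPL24 (0.44 ± 0.07), RPS15 (0.42 ± 0.07) and RPL14 (0.34 ± 0.06) were examples. RPL22 rose by 0.39 in its brightest probe set and by 0.27 and 0.23 in the next brightest ones, while 2 dimmer probe sets of that gene fell, by 1.86 and 0.77 on the log2 scale. Adjusted over the list alone, 15 rose, and camera called the list higher (adjusted p = 0.00423). With an estimated correlation (0.69 for this list) the call was lost (adjusted p = 0.853), in a setting that called 0 lists on 2 residual degrees of freedom. It was also lost with fry (adjusted p = 0.206). After quantile normalization the list had a median of 0.0021 and 1 rise and 1 fall (camera adjusted p = 0.99). Without KMT2D siRNA array a 0 members rose and without array b 1, with a median of 0.15 and 1 fall without control array a, and over 18 alternatives the camera adjusted p ran from 1.84e-05 to 0.99. RPL22, RPS15 and RPL14 did not pass without array a (adjusted p = 0.0772, 0.0913 and 0.112) or array b (0.0669, 0.0639 and 0.148), nor did RPL24 without array a (0.0931). RPS15 (0.065, adjusted p = 0.967) and RPL14 (0.065, 0.835) did not pass without _x_at and _s_at probe sets, and RPL22, RPL24, RPL14 and RPS15 did not with dim values raised (0.0629, 0.119, 0.0727 and 0.131), nor the first 3 after quantile normalization (0.118, 0.116 and 0.264). The brightest probe sets, among which these genes lie, had a median change of 0.20, the 18 bacterial and phage control probe sets were all higher on KMT2D siRNA arrays (median 0.18), against a median of 0.24 between control arrays b and a. The actin and GAPDH 3'/5' ratios were as given for mitosis.

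Of 23 measured epithelial and junction genes 7 rose and 1, the desmosomal DSP (-0.50), fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0814, 0.0408 with a variance trend and 0.789 with an estimated correlation). The keratin KRT8 went from 6112 ± 214 to 16611 ± 912 (1.44 ± 0.07) and its partner KRT18 from 19151 ± 279.9 to 34287 ± 537 (0.84 ± 0.05). Of 28 mesenchymal genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.648). The rises were COL6A1, a collagen chain (1.13 ± 0.13), S100A4 (0.74), CCN1 (0.71), vimentin, VIM (0.26), and LOXL2 (0.28), and the fall was smooth muscle actin, ACTA2 (-1.01). SPARC, a matrix protein, had signals of 69.5 ± 11.3 and 27.1 ± 3.96 and did not pass (adjusted p = 0.122). In the TGF-beta and SMAD pathway 7 of 23 rose and 4 fell (10 and 4 adjusted over the list alone; median 0.39, camera adjusted p = 0.0814). Of random lists matched on brightness 0.28% had a median as high as that of the TGF-beta list, and 3.69% as high as that of the epithelial list. ID2, a target gene of the pathway, went from 666 ± 24 to 1882 ± 28.2 (2.82-fold), and SKIL, a SMAD co-repressor, from 1276 ± 261 to 429 ± 4.97 (-1.56 ± 0.16). The rises numbered 4 and 3 in the epithelial, 3 and 3 in the mesenchymal and 4 and 4 in the pathway list without KMT2D siRNA array a and array b, and the falls 1 and 0, 0 and 0, and 3 and 2, with 2 mesenchymal falls without control array a. COL6A1 (0.14, adjusted p = 0.891) and SKIL (-0.73, 0.217) did not pass with the mean of their probe sets or with dim values raised (0.0775 and 0.0654).

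Other signalling genes changed without a shared direction that passed camera. Of 17 Notch pathway genes 4 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.21), with rises in the ligand JAG1 from 5239.8 ± 71.8 to 11039 ± 166 (1.07 ± 0.07) and in the DNA-binding effector RBPJ from 973 ± 23.9 to 2191 ± 34.4 (1.17 ± 0.10). The ligand JAG2 (0.43) and the glycosyltransferase LFNG (1.73) also rose, and NRARP fell (-0.64). Of 22 Wnt pathway genes 2 rose, DKK1 (0.66) and CD44 (0.31), and 2 fell, APC (-0.78) and FZD7 (-0.58), with the same counts adjusted over the list alone (adjusted p = 0.211). RNF43 and DKK3 had control signals of 15.6 and 11.1 and did not pass (log2 changes 1.54 ± 0.64 and 2.07 ± 0.69). In the RAS-MAPK and PI3K pathway 8 of 22 rose and 5 fell (9 and 5 adjusted over the list alone; adjusted p = 0.584). Of random lists matched on brightness, 0.3% had a median as high as the Wnt list (0.40). For the RAS-MAPK and PI3K list (0.23) the share was 1.88% and for the Notch list (0.20) 7.31%. This comparison takes no account of correlation between genes. PIK3CB, a catalytic subunit of phosphoinositide 3-kinase, went from 4276 ± 122 to 531 ± 23.1 (8.05-fold lower, -3.01 ± 0.10), and the kinase MAP2K1 from 1612 ± 70.6 to 466 ± 28.9 (-1.79 ± 0.12). MAP2K2, its close relative, which was singled out after its values were seen, rose from 3171 ± 216 to 7463 ± 310.2 (1.24 ± 0.08). Among Notch genes 2 and 2, among Wnt genes 1 and 1 and among RAS-MAPK and PI3K genes 4 and 5 rose without KMT2D siRNA array a and array b, and 0 and 1, 0 and 1, and 2 and 3 fell; 4 Wnt genes rose without control array a and 0 Notch genes fell without control array b. JAG1 did not pass with the mean of its probe sets (0.54, adjusted p = 0.0531), nor RBPJ without _x_at and _s_at probe sets (0.23, 0.874). The other bright JAG1 probe sets rose by 0.99, 0.98 and 1.34 on the log2 scale, and its dim ones changed by -1.71 and 0.58 without passing. Another bright RBPJ probe set rose by 1.35.

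**Figure D3:**
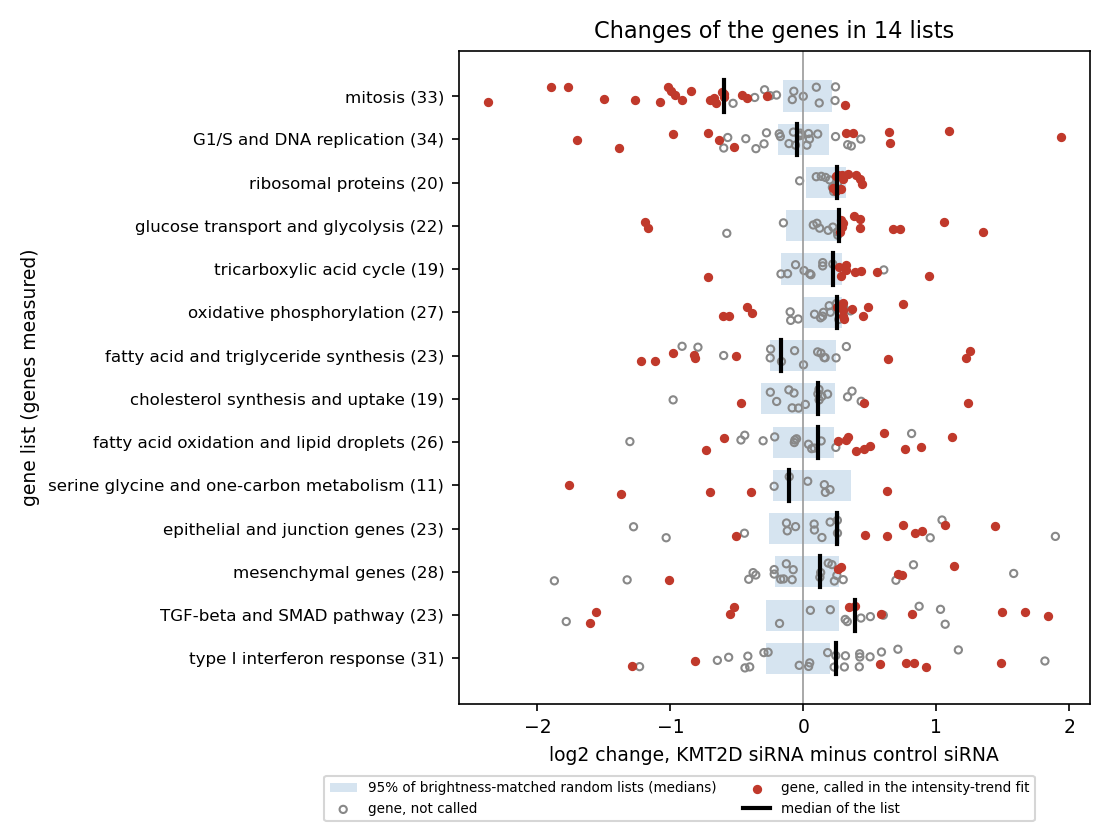
log2 change of each measured gene (horizontal axis) in 14 of the gene lists (vertical axis), with genes called in the intensity-trend fit filled, the list median as a black bar and the central 95% of medians of brightness-matched random lists shaded. The median of the mitosis list, -0.60, lies below its shaded range of -0.15 to 0.22, and that of the ribosomal list, 0.25, lies within its range of 0.023 to 0.32.

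The median mean log2 value was 4.30 for endothelial, 4.58 for endocrine, 4.71 for leukocyte, 4.89 for acinar and 5.68 for ductal markers and 6.496 for fibroblast and stellate cell markers, against 5.93 over all probe sets. The list medians use the brightest probe set of each gene, so the 2 scales are unlike. By that probe set 12154 of all 19775 genes lay at or above 5.93, and a typical gene was brighter than that. Bright members included the ductal factor SOX9 (control signal 6797), the granin gene SCG2 (13460.5) and the collagen chain COL3A1 (1297), picked after their values were seen. Of 13 fibroblast and stellate cell markers 2 rose and 1 fell (3 and 1 adjusted over the list alone). The pericyte gene RGS5 went from 8327 ± 621 to 13328 ± 50.3 (0.68 ± 0.07) and the collagen chain COL1A2 from 7128 ± 349 to 11036 ± 369.6 (0.63 ± 0.07), while DCN, LUM, PDGFRB and PDGFRA had control signals of 106, 35.2, 46.4 and 31.6, against a median over probe sets of 59.9. ACTA2, which the mesenchymal list also holds, was the fall. Among 11 ductal markers KRT19 rose (0.63 ± 0.15), also when adjusted over the list alone, and CFTR was near the noise at 34.2 ± 6.79 and 24.3 ± 0.162. The acinar list had 1 rise among 9 (0 adjusted over the list alone), in PRSS3 (2.38), with signals of 11.2 ± 2.91 and 44.7 ± 4.15 for CPB1 and 61.6 ± 1.62 and 16.5 ± 4.88 for CEL, which did not pass. The endothelial list had 1 rise among 10 (0 adjusted over the list alone), in CDH5 (0.85 ± 0.23), and TIE1 had signals of 4.02 ± 2.21 and 23.4 ± 1.17. Of 12 endocrine and 12 leukocyte markers 0 changed, also when adjusted over each list alone, with control signals of 147 for CHGB, 4.78 for INS, 37.2 for TYROBP and 5.18 for NKG7. Camera gave adjusted p = 0.654 for the fibroblast, 0.607 for the ductal, 0.79 for the acinar, 0.255 for the endothelial, 0.952 for the endocrine and 0.607 for the leukocyte list. KRT19 and CDH5 did not pass without KMT2D siRNA array a (adjusted p = 0.124 and 0.114) or array b (0.112 and 0.241), and CDH5 did not without control array b (0.0745), where KRT19 had a log2 change of 0.38. KRT19 (0.28, adjusted p = 0.45) and RGS5 (0.28, 0.136) did not pass with the mean of their probe sets, nor COL1A2 without _x_at and _s_at probe sets (0.081, 0.87). The other bright RGS5 probe sets rose by 0.70, 0.72 and 0.66 on the log2 scale, and its dimmer ones changed by -0.67 and -0.44 without passing. Another bright COL1A2 probe set rose by 0.79. With dim values raised KRT19 (adjusted p = 0.251), CDH5 (0.119) and RGS5 (0.0524) did not pass, nor KRT19 (0.0751) and CDH5 (0.0649) with centred arrays. Without control array a the ductal and endothelial lists had 2 rises each and the endocrine and leukocyte lists 1 each, while with either KMT2D siRNA array left out the ductal, acinar and endothelial lists had 0 and the fibroblast list 0 falls.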

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

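Cyclic loess, camera with a variance trend and all alternatives to the intensity-trend fit were chosen after seeing the data. KMT2D stayed lower in the designed fit under its 13 alternatives (log2 change -2.30 to -2.18, adjusted p 1.84e-04 to 0.461). It passed with probe sets at or above the median level (-2.26, adjusted p = 0.0169), with a floor at the 25th percentile (-2.26, 0.0402) and with the intensity trend (-2.26, 1.84e-04). The designed fit called 1788 probe sets higher and 2535 lower, and 1237 genes higher and 1638 lower, at or above the median level. With the floor it called 590 and 766 probe sets and 709 and 851 genes, and with the intensity trend 2980 and 3225 probe sets and 1854 and 2006 genes. The other alternatives to it, treat at 1.2-fold included, left both counts at 0. Starting from the intensity-trend fit, 1 variance prior gave 0 for all 4 counts and an adjusted p of 0.192 for KMT2D (-2.26). Centring each array on its median gave 1387 probe sets higher and 1627 lower and 1148 and 1213 genes. The floor gave 526 and 627 probe sets and 758 and 854 genes. The mean of all probe sets gave 992 and 1025 genes, and leaving out probe sets ending in _x_at or _s_at gave 1142 genes higher. Without 1 array, probe sets ran from 1042 to 3557 higher and 1749 to 3009 lower and genes from 634 to 2447 higher and 995 to 2202 lower, where the lone array of a group is assumed to vary like the other group. Of the 3860 genes, 1617 and 1607 were shared with the calls made without KMT2D siRNA array a and b. The replicate letters did not pair the arrays (correlation of same-letter deviations -0.0069 across genes). With the letter as a block, the designed fit called 0 genes and the intensity-trend fit 2289 higher and 2405 lower, including all 3860; the glycolysis list had a median of 0.27 and adjusted p = 0.105 in the paired design. Camera called 1 list after quantile normalization, with cyclic loess, with the mean of probe sets and without _x_at and _s_at probe sets, 5 with the floor, 6 with the intensity trend, 6 with a variance trend, 0 with an estimated correlation and 1 to 5 without 1 array; fry called 1. The glycolysis list lost its call after quantile normalization (0.16), median centring (0.30) and cyclic loess (0.15), with the mean of probe sets (0.26), without _x_at and _s_at probe sets (0.34), with an estimated correlation (0.27), by fry (0.27) and without control b or either KMT2D siRNA array (medians without 1 array ran from 0.24 to 0.30). The ribosomal list turned its camera direction after quantile normalization (median 0.0021, adjusted p = 0.99). It lost its call with cyclic loess (0.029), the mean of probe sets (0.22), no _x_at or _s_at probe sets (0.16), an estimated correlation (0.25), fry (0.25) and without either KMT2D siRNA array (adjusted p = 0.106 and 0.0606; medians without 1 array ran from 0.15 to 0.33). The mitosis list lost it with an estimated correlation (-0.60) and by fry (-0.60). Named genes reversed with the mean of probe sets were APAF1 (0.36), KDM3A (-0.30), RPL22 (-0.34), ATG3 (0.36) and LIPA (0.35), and without _x_at and _s_at probe sets EED (0.81), RPL22 (-1.86) and ATG3 (1.37). These settings use other probe sets of the gene. Among the reversed genes only RPL22 and ATG3 had another probe set called in the opposite direction. The other probe sets of KDM3A (mean log2 value 3.48), LIPA (2.32) and EED (5.80) were dim and did not pass, nor did those of APAF1. For the other results that moved the cause was not tested. With the mean of its 6 probe sets KMT2D changed by -0.44 (adjusted p = 0.616). The median change of all genes stayed between -0.072 and 0.041, and the share of calls that were higher was 48.0%, 45.6% to 48.6% under other scalings, 38.2% and 39.2% without KMT2D siRNA array a and b, 52.7% and 51.0% without control array a and b and 43.6% without _x_at and _s_at probe sets. Dim signal limits detection: duplicates differed by over 2-fold in 44.8% of control probe sets in the dimmest bin and 0.0820% in the brightest.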

Other observations

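Genes of stress and cell death changed in both directions after KMT2D siRNA. MCL1, an anti-apoptotic relative of BCL2, went from 6399 ± 1082 to 20573 ± 499 (1.69 ± 0.11), and APAF1, the scaffold of the apoptosome, from 701 ± 4.97 to 303 ± 30.2 (-1.21 ± 0.16) in its brightest probe set. Among 19 apoptosis regulators 4 rose and 2 fell (also adjusted over the list alone; camera adjusted p = 0.55), and among 22 p53 targets 2 rose and 4 fell (4 and 7 adjusted over the list alone; 0.763). RRM2B, a ribonucleotide reductase subunit, went from 833 ± 55.9 to 189 ± 40.6 (-2.15 ± 0.20), and TIGAR, a fructose bisphosphatase, rose (0.88 ± 0.09). HMOX1, the inducible heme oxygenase, went from 544 ± 16.6 to 1665 ± 187 (1.61 ± 0.13) and the small heat shock protein HSPB1 from 5254 ± 865 to 9908 ± 476 (0.92 ± 0.11), with 4 of 15 heat shock and oxidative stress genes rising and 2 falling (also adjusted over the list alone; 0.395). In the unfolded protein and integrated stress response 4 of 21 rose and 5 fell (5 and 6 adjusted over the list alone; 0.985), with rises in the chaperone genes PDIA4 (1.17 ± 0.10) and SDF2L1 (0.90 ± 0.15). The falls were ASNS (-1.06), ATF3 (-2.00), EDEM1 (-0.89), TRIB3 (-0.63) and ATF4 (-0.29), of which ATF4 is the transcription factor that drives the other amino acid response genes ASNS, ATF3 and TRIB3. Of 21 hypoxia genes outside glycolysis 3 rose and 2 fell (also adjusted over the list alone; 0.802), with rises in the brightest probe set of the demethylase KDM3A (0.90 ± 0.10) and the oxygen sensor EGLN1 (0.80 ± 0.09). Counts moved with single arrays. In the unfolded protein and integrated stress response 10 rose and 5 fell without control array b, 4 and 9 without control array a, and 2 and 3 without KMT2D siRNA array a. Among p53 targets 4 rose and 8 fell without control array a, 5 and 4 without control array b, 1 and 3 without KMT2D siRNA array a and 1 and 1 without array b. With either KMT2D siRNA array left out, 1 apoptosis regulator rose, 1 hypoxia gene fell and 1 heat shock gene fell. APAF1 had a log2 change of 0.36 (adjusted p = 0.523) and KDM3A of -0.30 (0.771) with the mean of their probe sets. SDF2L1 did not pass without KMT2D siRNA array a (adjusted p = 0.0606), nor EGLN1 (0.0746) and HSPB1 (0.096) with dim values raised to the 25th percentile.

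Inflammatory and immediate early genes also split. TNFAIP3, which restrains NF-kB signalling, fell from 2401 ± 290.3 to 937 ± 58.5 (-1.35 ± 0.12) while CCL20 rose, and 5 of 24 genes of NF-kB and inflammatory cytokines rose and 4 fell (also adjusted over the list alone; camera adjusted p = 0.783). Of 31 type I interferon response genes 5 rose and 2 fell (also adjusted over the list alone; 0.388), among them IFI35 (0.83 ± 0.15) and USP18 (-1.29 ± 0.28). Without KMT2D siRNA array a 0 of the 31 passed and without array b 3 did. IFI35 had an adjusted p of 0.0744 and 0.0749 without array a and array b, and USP18 of 0.1 without array a. Of 23 immediate early genes 4 rose and 6 fell (4 and 8 adjusted over the list alone; 0.634), with IER3 going from 8672 ± 1329 to 2751 ± 158 (-1.65 ± 0.11) and the phosphatase DUSP1 from 2752 ± 74.5 to 5963 ± 18.4 (1.12 ± 0.08). The siRNA machinery had 2 rises, in TNRC6A (1.19) and AGO2 (0.70), and 4 falls among 12 genes (also adjusted over the list alone; 0.287). DICER1, which cuts microRNA precursors, went from 2515 ± 41.7 to 1035 ± 63.2 (-1.28 ± 0.10), AGO4 from 1731 ± 223 to 539 ± 33 (-1.68 ± 0.14), PRKRA changed by -1.12 and TNRC6B by -0.93. Of 26 autophagy and lysosome genes 5 rose and 5 fell (11 and 7 adjusted over the list alone; 0.38), and ATG3 (-0.64 ± 0.08) and the lysosomal lipase LIPA (-0.57 ± 0.06) fell in their brightest probe sets. Of random lists matched on brightness 1.43% had a median as high as the autophagy and lysosome list (0.27) and 1.2% as high as the interferon list (0.24). In the inflammatory list 10 rose and 3 fell without control array b, 1 and 3 without KMT2D siRNA array a and 2 and 3 without array b. Among autophagy and lysosome genes 8 rose and 8 fell without control array a, 10 and 4 without control array b, and 1 and 2 with either KMT2D siRNA array left out, which also left 1 rise in the siRNA machinery. With the mean of their probe sets ATG3 (0.36, adjusted p = 0.162), LIPA (0.35, 0.726) and AGO4 (-0.90, 0.0785) did not pass, and the other ATG3 probe set rose by 1.37. USP18 (adjusted p = 0.111) and ATG3 (0.051) did not pass with dim values raised.

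The comparison of cell cycle lists and the count of splits below were chosen after the results were seen. Of the 3 splits of the 4 arrays into pairs, 1, the real one, called 3860 genes and the highest of the others called 0, and 3 splits are too few for a share under 0.05. The other splits put duplicates of a group on opposite sides, so any difference between the groups adds to the spread within pairs. Few or 0 calls would follow there whatever the source of that difference, and the count does not bear on KMT2D.

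The fall of mitosis genes was set against technical explanations. Of 10000 random lists matched on brightness, 0% had a median as low as -0.60, which argues against a brightness-dependent difference between arrays as its source. G1/S and replication genes had a median of -0.045, higher by 0.55 than the mitosis genes (two-sided permutation p = 0.00081 over 100000 draws across genes, which are not independent), which argues against a fall of all cell cycle genes alike. A difference in RNA integrity stays open. Control array b had mitosis genes lower than control array a by a median of 0.19 (bootstrap interval over genes 0.126 to 0.315), the direction of the KMT2D siRNA arrays. Its actin 3'/5' ratio was the lower and its GAPDH 3'/5' ratio the higher of the pair, so the order of integrity is not settled. The interval covers genes, which are correlated, and not the spread between arrays, so 1 array against its duplicate cannot test this explanation. Depletion of KMT2D, a change between cultures and an effect of the siRNA on other transcripts may each contribute, and the design separates none of them.

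The rise of ribosomal protein genes was set against the same technical explanations. Of random lists matched on brightness 21.43% had a median as high, so a brightness-dependent difference between arrays may account for it. Control array b also had these genes higher than control array a by a median of 0.175 (bootstrap interval over genes 0.117 to 0.214), and since the actin and GAPDH ratios order these arrays oppositely, an RNA integrity difference stays open. An effect of KMT2D depletion stays untested.

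For the rise of glycolysis genes, 3.25% of brightness-matched lists had a median as high, above the 2.5% set in advance, so a brightness-dependent difference between arrays stays a candidate source for part of it. Between the control arrays these genes differed by a median of -0.0413 (bootstrap interval -0.131 to 0.0713, positive toward the KMT2D siRNA level), an interval that includes 0, which with the opposite order of the actin and GAPDH ratios leaves an RNA integrity difference open. Depletion of KMT2D stays an open explanation.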
